A study of Arabidopsis thaliana with 18 samples.

How the data were processed

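Poly(A) RNA was sequenced from roots of 4-day-old Arabidopsis thaliana seedlings kept under 16 h of light and 8 h of dark. The 18 libraries fall into 6 groups of 3 by the genotype in their titles: wild type (WT), rab8d-2, and rab8d-2 combined with atm-2, sog1-1, nac044-1 or nac085-1. The genotype field of the rab8d-2 libraries names wild type, which contradicts their titles. The titles were followed, and RAB8D RNA in these libraries was 12.6% of WT. The libraries were made by oligo(dT) selection, per the submitters' notes.

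The deposited table gives 3 kinds of values for each of 25537 genes and each library. The estimated counts were made by the authors with RSEM 1.3.1. The transcript abundances (TPM) were scaled by the authors to a fixed sum per library. The deposited FPKM values are scaled by transcript length and library size. Between 1.56% and 1.75% of the estimated counts in a library carry decimals, and all estimated counts were rounded to whole numbers before testing. The aligner, genome build, annotation and strand were not given in the sources used here, so no coordinates are printed. Gene names and gene order came from a reference annotation that matched 25462 of the locus identifiers. The 75 others are 68 plastid and 7 mitochondrial identifiers, which were kept.

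Library totals lay between 20103600 and 20471200 estimated counts. The 20 most abundant genes took 3.88% to 5.29% of a library, and plastid and mitochondrial genes together 0.000765% to 0.00165%. Where a group had no counts of a gene, a floor of 3 counts over the group's 3 libraries gives a lower bound on the fold, and a group with 1 to 3 counts gives a ratio with a 95% exact binomial interval. These intervals and floors cover counting error only. No printed list median changes when such genes are set at their bound.

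Differences were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling (factors 0.970 to 1.02), the tool's own filter on low counts, which kept 19981 genes, and a quasi-likelihood test in a model with 1 mean per genotype fitted to all 18 libraries. P values were adjusted by Benjamini-Hochberg within each of the 11 comparisons, and genes with an adjusted p under 0.05 count as changed. Adjusted p values of genes in the text come from this test, and ± after a log2 fold change is its standard error with n = 3 per group. Normalised counts (CPM) are counts relative to library size after TMM scaling, given with the SD.

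The spread between libraries of a genotype was small, with a common dispersion of 0.000566, or a biological coefficient of variation of 2.38%. In pairs of libraries of a genotype the variance was 1.33 to 2.16 times that of counting alone, so no library is a copy of another. The tests measure the spread between these libraries, which the labels call biological replicates without saying how separately the plants were grown. Replicate numbers do not pair libraries across genotypes in the labels, and no block was used.

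Gene lists were tested with camera from limma 3.58.1 with a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the lists within a comparison. The test was repeated with the correlation estimated from the data and with fry. Members past the threshold were counted over all genes tested and again adjusted over the list alone. Before the data were examined, 26 lists were fixed: DNA damage response, recombination and end joining, cyclin-dependent kinase inhibitors, G2 and mitosis, S phase, plastid genome, mitochondrial genome, photosynthesis, plastid translation, plastid chaperones and proteases, cytosolic heat shock, unfolded protein response, mitochondrial stress, oxidative stress, salicylate defence, root meristem, cytokinin response, auxin response, iron deficiency, phosphate starvation, and markers of root hair, endodermis, xylem, phloem, root cap and shoot. A set of 5 further lists was chosen after the data were seen: clock genes with a peak around dawn, clock genes with a peak around dusk, jasmonate, touch and wounding, and cold and dehydration. Because these 5 lists were chosen from the same data, their p values are descriptive in every comparison and give no independent support. Some genes stand in more than one list: SMR4, SMR5, SMR7 and KRP6 in the DNA damage and kinase inhibitor lists, ZAT10 and ZAT12 in the oxidative stress and touch lists.

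Named genes followed a rule fixed before the data were examined. It takes the 5 mutated genes and the whole DNA damage list. In rab8d-2 against WT and in each double mutant against rab8d-2 it takes the 8 highest and 8 lowest log2 fold changes, and 4 and 4 elsewhere. These come from changed genes with a mean log2 CPM of at least 1 whose 3 libraries of one genotype all lie above the 3 of the other. From each list it takes up to 4 members with the smallest p in rab8d-2 against WT and up to 3 elsewhere. Members named from the lists chosen later were picked after their values were seen.

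Reversal was counted as the genes changed at least 2-fold in rab8d-2 against WT that changed the other way in a double mutant against rab8d-2. Both comparisons share the rab8d-2 libraries, so the count was set beside 10 simulated data sets in which the double mutant had the rab8d-2 means, and beside the number given by independent lists.

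Alternatives were DESeq2 1.42.0 and its size factors in edgeR, upper quartile scaling, no filter or a filter of 1 CPM in at least 3 libraries, only the 6 libraries of a comparison, a replicate block, organelle genes left out, limma on log2(TPM + 1), and each library left out in turn. Genes of chromosome 1 were left out, and cell cycle genes and mutated genes were removed from the DNA damage list, only after the data were seen. The scalings moved the median log2 fold change of all genes by at most 0.0667. With upper quartile scaling the direction that held more of the changed genes switched in several comparisons, so counts of higher and lower genes are not a balance between the directions. No library or value column was left out of the main test.

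The procedure was tested on simulated data with the sizes and spread of the real libraries. All genotypes had the WT means, apart from planted changes in rab8d-2: 50 genes at each fold below and a list of 20 genes at 1.3-fold. Nearly all genes were thus unchanged, whereas 64.5% were called in the real comparison, so the rates may differ there. edgeR recovered 78% of 1.25-fold, 94% of 1.5-fold, 98% of 2-fold and 100% of 4-fold changes among 19531 genes, and 6.88% of its calls were false. DESeq2 recovered 66%, 94%, 96% and 100%, and limma 78%, 96%, 98% and 100%, with 1.02% and 8.52% of their calls false.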

Results

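RNA levels were measured in roots of 18 samples from 6 genotypes with 3 samples each. The rab8d-2 line carries a mutation in RAB8D, the plastid translation elongation factor EF-Tu. The double mutants add a mutation in ATM, the kinase that responds to DNA double-strand breaks, in SOG1, the transcription factor downstream of it, or in NAC044 or NAC085, related transcription factors that SOG1 regulates. Library totals were 20103600 to 20471200 estimated counts.

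RAB8D (AT4G20360) had 90.2 ± 2.62 normalised counts (CPM) (SD, n = 3) in WT and 11.4 ± 0.419 in rab8d-2, or 12.6% of WT (log2 fold change -2.98 ± 0.06, adjusted p = 1.72e-38), and 13.2 to 17.7 in the double mutants. In these it was higher than in rab8d-2, by 0.63 ± 0.08 (atm-2), 0.22 ± 0.08 (sog1-1), 0.36 ± 0.08 (the nac044-1 label) and 0.43 ± 0.08 (nac085-1), with adjusted p values from 1.4e-09 to 0.0284. The highest p is that of the sog1-1 double mutant, whose call was lost without replicate 1 (0.13, adjusted p = 0.261) or 3 (0.17, adjusted p = 0.137) of sog1-1 rab8d-2 or replicate 3 of rab8d-2 (0.19, adjusted p = 0.0998). ATM (AT3G48190) had 53.7 ± 3.02 in rab8d-2 and 5.51 ± 0.256 in atm-2 rab8d-2 (log2 fold change -3.28 ± 0.07, adjusted p = 8.33e-39). SOG1 (AT1G25580) had 25.0 ± 1.44 in rab8d-2 and 29.4 ± 1.40 in sog1-1 rab8d-2 (log2 fold change 0.23 ± 0.05, adjusted p = 0.000284), so its RNA level gives no check of that label. NAC085 (AT5G14490) was scarce, with 1.73 ± 0.402 in rab8d-2 and 0.915 ± 0.443 in nac085-1 rab8d-2 (log2 fold change -0.92 ± 0.26, adjusted p = 0.00248). Without replicate 3 of nac085-1 rab8d-2 the value was -0.59 with an adjusted p of 0.0506.

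NAC044 (AT3G01600) had 5.17 ± 0.712 normalised counts (CPM) in WT and 19.4 ± 0.588 in rab8d-2. In the libraries labelled nac044-1 rab8d-2 it had 159.8 ± 3.48, which is 8.22-fold higher than in rab8d-2 (log2 fold change 3.04 ± 0.04, adjusted p = 1.04e-43, n = 3). A loss of the RNA was thus not seen in these libraries, and they are named by their label throughout. The other double mutants had 14.4 ± 0.141 (atm-2), 16.9 ± 0.534 (sog1-1) and 13.01 ± 0.785 (nac085-1).

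**Figure D1:**
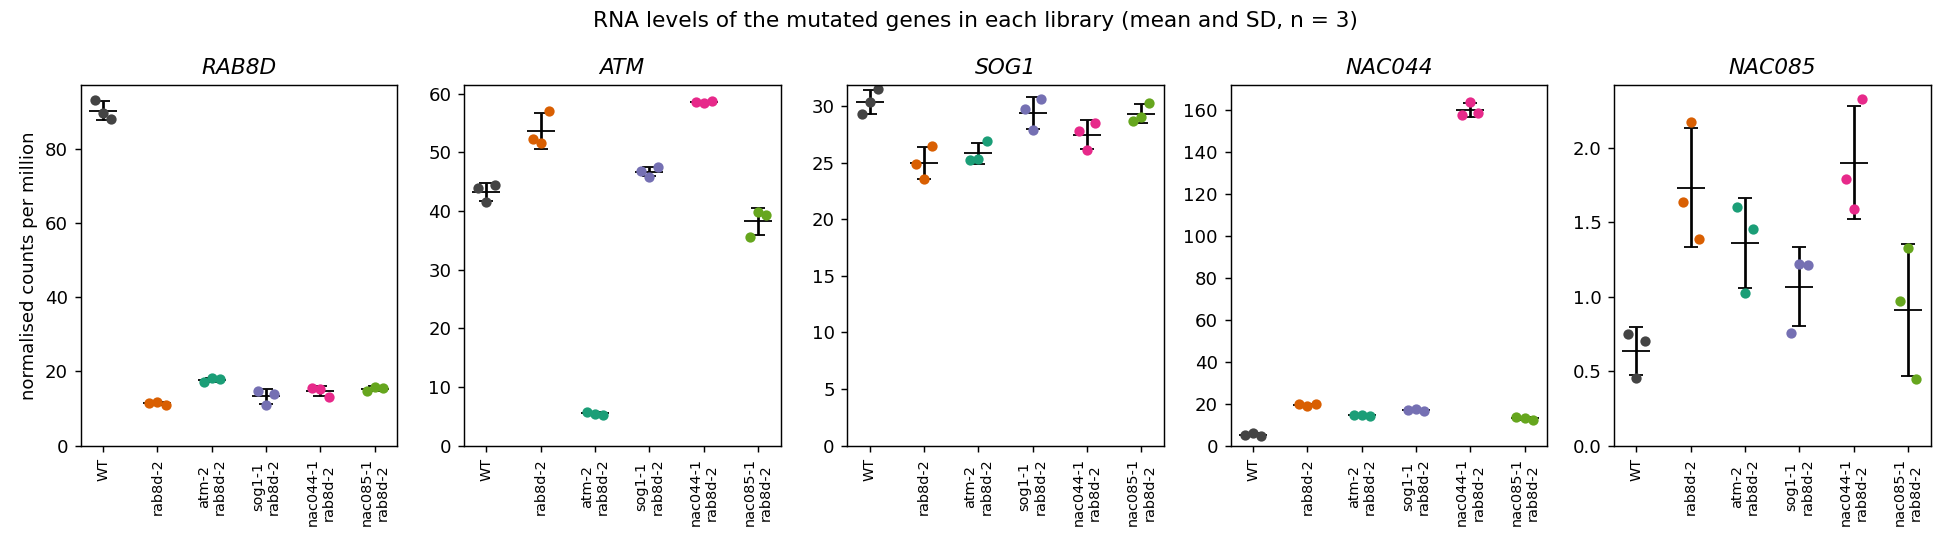
Normalised counts (CPM) (y axis) of the 5 mutated genes in each library of the 6 genotypes (x axis). Points are libraries, the long bar is the mean and the error bar the SD, n = 3. RAB8D is below 20 in every library with the rab8d-2 label, and NAC044 has a mean of 159.8 in the libraries labelled nac044-1 rab8d-2.

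The comparison of rab8d-2 with WT asks what changes when the plastid elongation factor is reduced. DNA damage response genes rose as a group, while nuclear photosynthesis genes and markers of endodermis, xylem and phloem fell. The steepest rises were AT5G45990 (85.9-fold, log2 fold change 6.42 ± 0.21), the ABC transporter gene ABCA9 (6.22 ± 0.32) and the transcription factor gene WRKY28 (6.14 ± 0.28). The dirigent protein gene DIR5 (5.11 ± 0.23) and the lipid transfer protein gene LTP5 (4.62 ± 0.11) were also among the highest. The steepest falls were SWEET11, a sucrose exporter, at 33.0-fold lower (-5.04 ± 0.10), UMAMIT17 of the amino acid transporter family (-4.88 ± 0.15), the light-harvesting genes LHB1B2 (-4.20 ± 0.11) and LHCA3 (-3.16 ± 0.18), the chlorophyll synthesis gene CRD1 (-3.27 ± 0.16) and the MADS-box genes AGL17 (-3.35 ± 0.13) and AGL42 (-3.11 ± 0.20).

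Of the 25 genes of the DNA damage list, 23 were higher and none lower in rab8d-2 than in WT, with the same counts adjusted over the list alone. The median log2 fold change was 0.62 (camera adjusted p = 4.06e-07, and adjusted p = 0.00103 with an estimated correlation). NAC103, a NAC transcription factor gene, rose by 2.17 ± 0.08 on the log2 scale and NAC044 by 1.91 ± 0.08. GMI1 rose by 1.35 ± 0.06 and the poly(ADP-ribose) polymerase PARP2 by 1.09 ± 0.06. The cell cycle inhibitor SMR5 (0.657 CPM in rab8d-2 and 0.217 in WT) and NAC085 were scarce and rose by 1.57 ± 0.43 and 1.44 ± 0.29. CYCB1;1, a cyclin also induced by DNA breaks, was higher by 0.93 and BRCA1 by 0.50. The 2 members that were not called were SMR4 (-0.19) and WEE1 (0.05). Markers of xylem (median -0.86), phloem (-0.83) and endodermis (-0.63) moved down in the same libraries.

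Cell cycle genes moved less. Of 20 S phase genes 14 were higher and none lower (median 0.19, adjusted p = 0.117), with RNR2A, a ribonucleotide reductase subunit, at 0.69 ± 0.06. Of 28 genes of G2 and mitosis 8 were higher and 4 lower (median 0.10, adjusted p = 0.418). Of 16 genes of recombination and end joining 5 were higher over all genes and 4 adjusted over the list alone (median 0.07, adjusted p = 0.364), the largest being HOP2 (2.37-fold higher). Of 20 kinase inhibitor genes 4 were higher and 5 lower (median -0.12, adjusted p = 0.897), with KRP6 at 0.78 ± 0.07 and KRP1 at -1.06 ± 0.10.

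**Figure D2:**
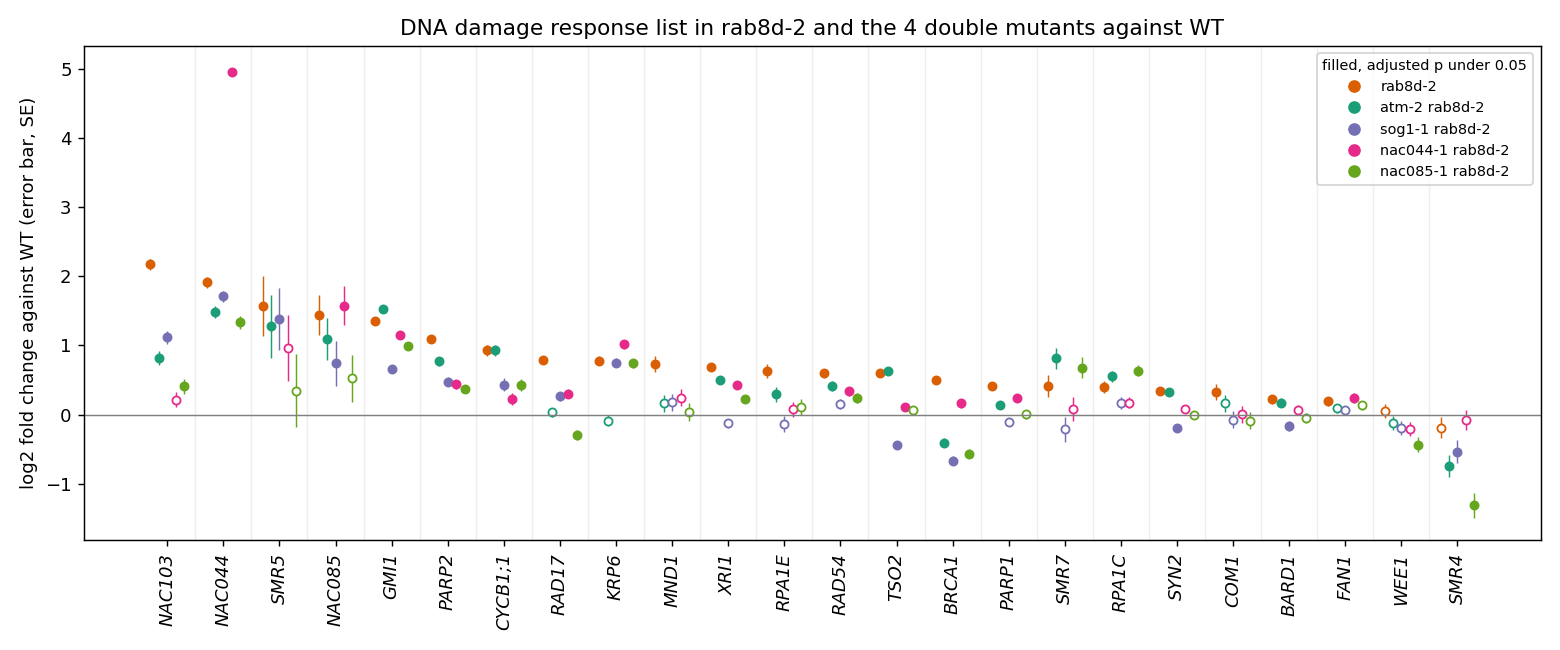
Log2 fold change against WT (y axis, error bars SE, n = 3 per group) of 24 genes of the DNA damage list (x axis) in rab8d-2 and the 4 double mutants. Filled points have an adjusted p under 0.05. NAC103 is at 2.17 in rab8d-2 and at 0.21 in the libraries labelled nac044-1 rab8d-2.

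Of the 24 photosynthesis genes tested, 20 were lower and 1 higher in rab8d-2 (median -1.26, adjusted p = 3.58e-06, and adjusted p = 0.00147 with an estimated correlation). PSBO1, of the oxygen-evolving complex, was at -2.30 ± 0.09, ATPC1, a subunit of the plastid ATP synthase, at -2.04 ± 0.10 and the Rubisco activase gene RCA at -1.27 ± 0.06. The member that was higher was RBCS3B, with 27 counts over the rab8d-2 libraries and 0 over those of WT, which is at least 8.64-fold higher. Genes for plastid ribosomal proteins and translation factors were lower in 19 and higher in 1 of 30 (median -0.24, adjusted p = 0.148). SCO1, a plastid elongation factor, was at -0.89 ± 0.05 and FUG1, a plastid initiation factor, at -0.91 ± 0.06. Plastid chaperones and proteases were higher in 2 and lower in 5 of 12 (median -0.04, adjusted p = 0.562). Only 6 of the 68 plastid identifiers passed the filter on low counts in these poly(A) libraries. All 6 were higher in rab8d-2 (median 2.58, adjusted p = 0.117), ATCG00190 by 1.85 ± 0.22. Apart from ATCG00190, their WT means lay between 0.0500 (ATCG00040) and 0.184 CPM (ATCG01130), so they passed the filter through groups where they were higher. Their shared direction is thus partly set by the filter. Of 5 mitochondrial identifiers tested 3 were lower, and 2 adjusted over the list alone (median -0.76, adjusted p = 0.788).

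Stress lists other than DNA damage gave mixed pictures in rab8d-2. Mitochondrial stress genes were higher in 9 and lower in 3 of 15 (median 0.20, adjusted p = 0.0251), a call that was lost with an estimated correlation (adjusted p = 0.205). NDB4, an alternative NADH dehydrogenase of mitochondria, rose by 3.61 ± 0.18, UPOX by 2.24 ± 0.13 and the transcription factor gene NAC013 by 0.84 ± 0.05, while DIC2, a mitochondrial carrier, was at -0.59 ± 0.03. Oxidative stress genes were lower in 10 and higher in 3 of 18, or 10 and 4 adjusted over the list alone (median -0.15, adjusted p = 0.0296, and adjusted p = 0.205 with an estimated correlation). Cytosolic heat shock genes were lower in 5 of 6 (median -0.51, adjusted p = 0.117), genes of the unfolded protein response higher in 6 of 7 (median 0.20, adjusted p = 0.117), and salicylate defence genes higher in 1 and lower in 2 of 4 (median -0.46, adjusted p = 0.117), with WRKY70 at -2.23 ± 0.09.

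Markers of endodermis, xylem and phloem were lower in rab8d-2. All 8 endodermis markers fell (median -0.63, adjusted p = 0.000855, and 0.0147 with an estimated correlation), among them ESB1 of the Casparian strip at -0.71 ± 0.03. Xylem markers fell in 6 of 7 (median -0.86, adjusted p = 7.21e-07, and 0.00379 with an estimated correlation), CESA4, a cellulose synthase of secondary walls, being at -1.16 ± 0.04. Phloem markers fell in 5 of 6 (median -0.83, adjusted p = 0.000598, and 0.0113 with an estimated correlation), SEOR2 of the sieve elements being at -1.55 ± 0.06 and the sucrose transporter SUC2 at -1.06 ± 0.06. Root hair markers were lower in 6 of 7 (median -0.59, adjusted p = 0.0991). Root cap markers had 1 of 4 higher, and none adjusted over the list alone (median 0.15, adjusted p = 0.794).

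Of 19 meristem genes 12 were higher and 5 lower in rab8d-2 (median 0.19, adjusted p = 0.14). ERF114, a transcription factor of the kind active after injury, was at 3.73 ± 0.17, PLT3 of the stem cell niche at 1.07 ± 0.05 and UPB1, a regulator of peroxidase genes, at -1.06 ± 0.06. Auxin response genes were higher in 5 and lower in 3 of 11, or 5 and 4 adjusted over the list alone (median 0.10, adjusted p = 0.328), with GH3.3, an auxin-conjugating enzyme, 11.3-fold higher. Cytokinin response genes were higher in 3 and lower in 4 of 9 (median -0.09 with a mean of 0.01, adjusted p = 0.911), iron deficiency genes higher in 2 and lower in 5 of 11 (median -0.28, adjusted p = 0.562) and phosphate starvation genes lower in 3 of 8 (median -0.09, adjusted p = 0.661). Of 3 shoot markers tested, CER6, a wax synthesis gene, was at 3.19 ± 0.25 and CER1, another, at -1.65 ± 0.16, 1 higher and 1 lower (median 0.41, adjusted p = 0.788).

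In the lists chosen after the data were seen, touch and wounding genes were lower in 9 and higher in 2 of 12 in rab8d-2 (median -0.53, adjusted p = 0.000171, and 0.02 with an estimated correlation). Dawn clock genes were lower in 5 of 6 (median -0.61, adjusted p = 0.297) and dusk clock genes higher in 2 and lower in 4 of 7 (median -0.17, adjusted p = 0.813). Jasmonate genes were higher in 6 and lower in 6 of 15 (median 0.06, adjusted p = 0.813). Cold and dehydration genes were higher in 1 and lower in 2 of 5, with a median of -0.24 against a camera rank in the upward direction (adjusted p = 0.351).

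In all, 6325 genes were higher and 6568 lower in rab8d-2 than in WT of 19981 tested, with 821 and 1061 changed at least 2-fold. Libraries of a genotype lay so close together that small differences passed the threshold. With upper quartile scaling the share of changed genes that were higher went from 49.1% to 56.6%.

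**Figure D3:**
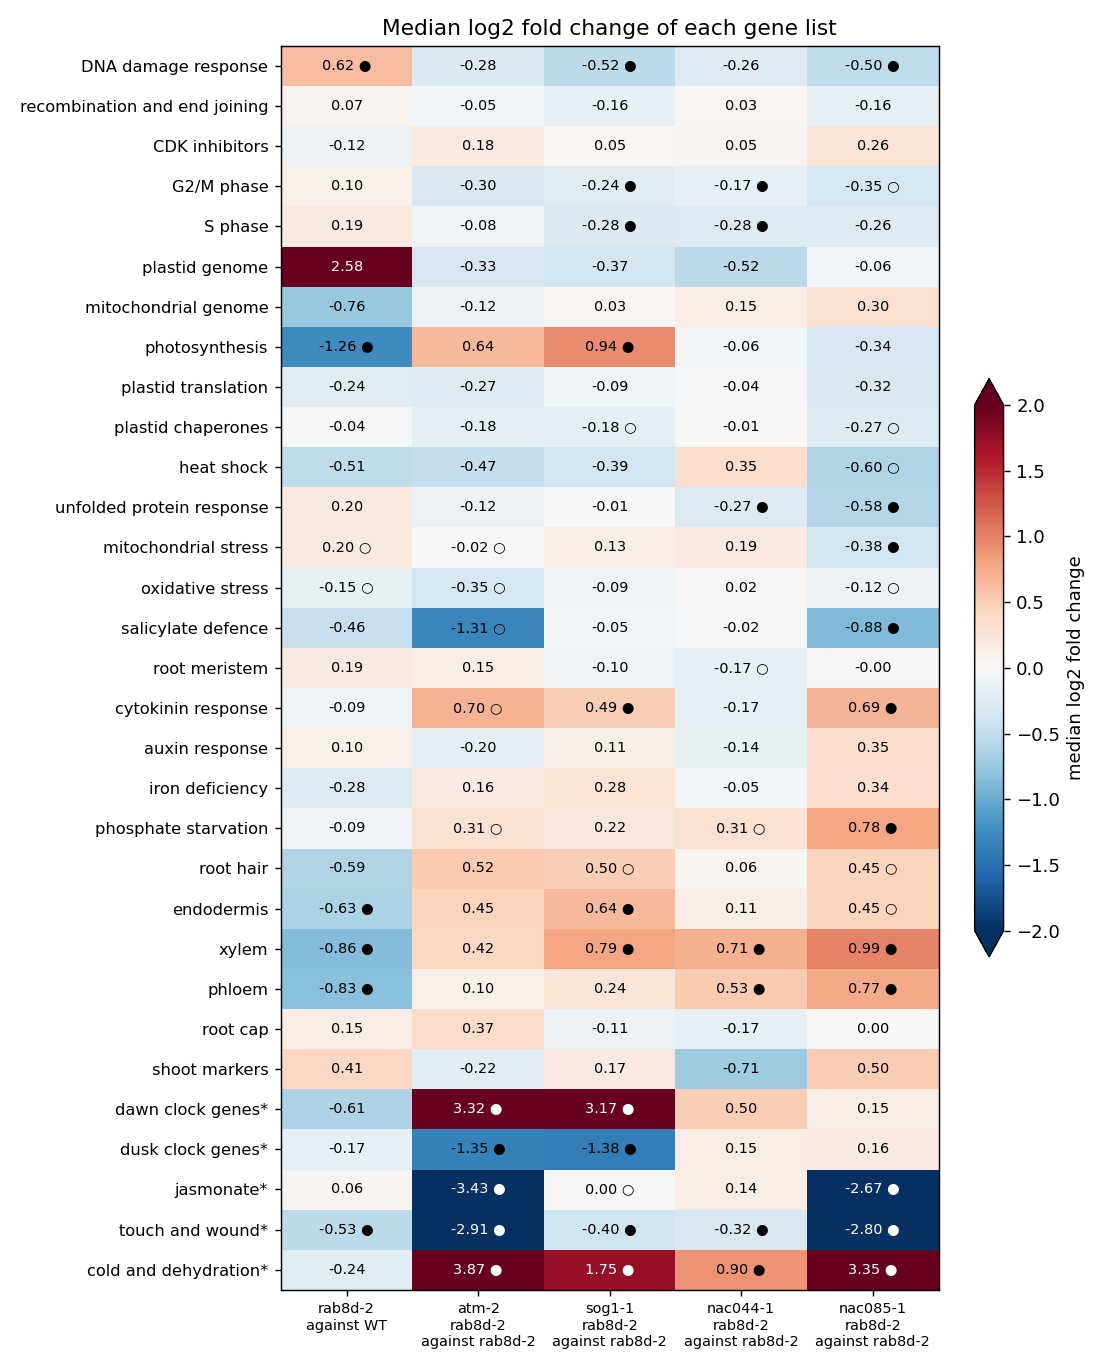
Median log2 fold change of each gene list (vertical axis) in rab8d-2 against WT and in each double mutant against rab8d-2 (horizontal axis), as colour and number. Filled circles mark an adjusted p under 0.05 with both the preset and an estimated correlation, open circles with the preset alone, and stars the lists chosen after the data were seen; the xylem median is -0.86 in rab8d-2 and 0.42 to 0.99 in the double mutants.

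The comparison of atm-2 rab8d-2 with rab8d-2 asks which changes of rab8d-2 move with the ATM kinase. The DNA damage list had 13 members lower and 2 higher of 25, the same adjusted over the list alone (median -0.28, adjusted p = 0.214, and a median of -0.17 without rab8d-2 replicate 3). NAC103 was at -1.36, BRCA1 at -0.91, KRP6 at -0.86 and RAD17 at -0.76, whereas CYCB1;1 (0.00) and SMR5 (-0.30) were not called, and SMR7 (0.40) and GMI1 (0.17) were higher. Genes of G2 and mitosis were lower in 20 and higher in 1 of 28 (median -0.30, adjusted p = 0.219) and S phase genes higher in 3 and lower in 6 of 20, or 2 and 6 adjusted over the list alone (median -0.08, adjusted p = 0.869). In the same libraries dawn clock genes had a median of 3.32 and jasmonate genes of -3.43.

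Among the steepest rises in atm-2 rab8d-2 were STH (4.75 ± 0.11), the ribonuclease gene RNS1 (4.59 ± 0.08), the dawn clock genes CCA1 (4.51 ± 0.15) and LHY (3.93 ± 0.16), GolS3, a galactinol synthase of the cold response (4.39 ± 0.10), and the cold-induced gene KIN2 (4.03 ± 0.05). AT3G45260 had 0 counts in atm-2 rab8d-2 and 266 in rab8d-2, at least 87.8-fold lower. This gene lies on the same chromosome as ATM, and a difference carried along with the atm-2 allele was not tested for it. DDF1 (-6.09 ± 0.08), the jasmonate regulator ORA47 (-5.84 ± 0.10), RRTF1 (-5.73 ± 0.05) and WRKY40 (-5.40 ± 0.05), genes of fast stress responses, were also among the lowest. The p values of the 5 lists that follow describe the size of the shift only, since the lists were chosen from these data. As whole lists chosen after the data were seen, all 6 dawn clock genes were higher (adjusted p = 6.01e-17), 6 of 7 dusk clock genes lower (median -1.35, adjusted p = 6.5e-12), all 15 jasmonate genes lower (adjusted p = 7.33e-84), all 12 touch and wounding genes lower (median -2.91, adjusted p = 7.01e-77) and all 5 cold and dehydration genes higher (median 3.87, adjusted p = 4.04e-29), and all 5 calls held with an estimated correlation.

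Among the fixed lists, cytokinin response genes were higher in 7 and lower in none of 9 in atm-2 rab8d-2 (median 0.70, adjusted p = 0.00337, and 0.051 with an estimated correlation), with the response regulators ARR9 at 1.17 ± 0.05 and ARR4 at 1.11 ± 0.04. Salicylate defence genes were lower in 4 of 4 (median -1.31, adjusted p = 0.00337, and 0.051 with an estimated correlation). Mitochondrial stress genes were higher in 4 and lower in 7 of 15 (median -0.02, mean -0.77, adjusted p = 0.00212, and 0.098 with an estimated correlation), DIC2 being at -3.25 ± 0.04. Oxidative stress genes were lower in 12 and higher in 6 of 18 (median -0.35, adjusted p = 0.0107, and 0.174 with an estimated correlation) and phosphate starvation genes higher in 4 and lower in 1 of 8 (median 0.31, adjusted p = 0.00573, and 0.098 with an estimated correlation). Photosynthesis genes were higher in 13 and lower in 5 of 24, or 14 and 5 adjusted over the list alone (median 0.64, adjusted p = 0.176), and xylem markers higher in 6 of 7 (median 0.42, adjusted p = 0.161). In all, 6330 genes were higher and 5969 lower, with 906 and 1080 changed at least 2-fold.

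The comparison of sog1-1 rab8d-2 with rab8d-2 asks which changes of rab8d-2 move with SOG1. The DNA damage list was lower as a group, with 21 of 25 members lower over all genes, 22 adjusted over the list alone, and none higher (median -0.52, adjusted p = 9.23e-09, and 0.00045 with an estimated correlation). BRCA1 was at -1.16, NAC103 at -1.05, TSO2, a ribonucleotide reductase subunit, at -1.04, GMI1 at -0.69, PARP2 at -0.62 and CYCB1;1 at -0.49. NAC044 was at -0.20, and SMR5 (-0.19) was not called. S phase genes were lower in 17 of 20, or 18 adjusted over the list alone (median -0.28, adjusted p = 0.00111, and 0.0102 with an estimated correlation), and genes of G2 and mitosis in 17 of 28, or 18 adjusted over the list alone (median -0.24, adjusted p = 0.00272, and 0.0102 with an estimated correlation). Xylem markers (median 0.79) and dawn clock genes (median 3.17) were higher in the same libraries.

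Several groups that had fallen in rab8d-2 were higher in sog1-1 rab8d-2 than in rab8d-2. Photosynthesis genes were higher in 18 of 24 (median 0.94, adjusted p = 5.47e-07, and 0.000863 with an estimated correlation), PSBO1 at 1.97 ± 0.09 and RCA at 1.70 ± 0.06. Their median was also raised in atm-2 rab8d-2, which shares the dawn clock shift, and lowered in nac085-1 rab8d-2, which does not. An effect of sog1-1 on them cannot be told apart from the clock shift. All 8 endodermis markers (median 0.64, adjusted p = 5.47e-07, and 0.00107 with an estimated correlation) and all 7 xylem markers (adjusted p = 3.05e-09, and 0.00101 with an estimated correlation) were higher, XCP1, a protease of dying xylem cells, at 0.93 ± 0.03. Phloem markers were higher in 4 of 6 (median 0.24, adjusted p = 0.0719). Root hair markers were higher in 6 and lower in 1 of 7 (median 0.50, adjusted p = 0.00812, and 0.0882 with an estimated correlation) and cytokinin response genes higher in 7 of 9, or 8 adjusted over the list alone (median 0.49, adjusted p = 0.00131, and 0.0102 with an estimated correlation). Plastid chaperones and proteases were lower in 7 and higher in 3 of 12 (median -0.18, adjusted p = 0.0359, and 0.0902 with an estimated correlation).

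The steepest rises in sog1-1 rab8d-2 were the clock genes CCA1 (4.85 ± 0.14), LHY (4.15 ± 0.15) and LNK2 (3.56 ± 0.05), the metal reductase gene FRO5 (4.33 ± 0.18), the alcohol dehydrogenase gene ADH1 (3.70 ± 0.09) and SWEET11 (3.62 ± 0.13). AT1G35115 had 0 counts in sog1-1 rab8d-2 and 5256 in rab8d-2, at least 1661-fold lower, and SADHU1-2 had 0 and 2958, at least 935-fold lower. AT1G27180 was at -5.45 ± 0.12 and MRD1 at -4.19 ± 0.20. AT1G35115, SADHU1-2 and AT1G27180 belong to a cluster of lowered genes near SOG1 that is weighed further below. Their fall can therefore not be assigned to the loss of SOG1 activity. Of the lists chosen after the data were seen, all 6 dawn clock genes were higher (adjusted p = 1.68e-43), all 7 dusk clock genes lower (median -1.38, adjusted p = 6.7e-32), 10 of 12 touch and wounding genes lower (median -0.40, adjusted p = 2.1e-07) and all 5 cold and dehydration genes higher (median 1.75, adjusted p = 1.48e-16), calls that held with an estimated correlation. Jasmonate genes were higher in 4 and lower in 7 of 15 (median 0.00, mean -0.19, adjusted p = 0.0146, and 0.0781 with an estimated correlation). In all, 5725 genes were higher and 5194 lower, with 673 and 308 changed at least 2-fold. Without the genes of chromosome 1, which carries SOG1, 463 and 168 genes were changed at least 2-fold.

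The comparison of the libraries labelled nac044-1 rab8d-2 with rab8d-2 was made by label, since NAC044 RNA was higher in them. It was the comparison with rab8d-2 that changed the fewest genes at least 2-fold, 148 higher and 331 lower. The DNA damage list had 18 members lower, 19 adjusted over the list alone, and 2 higher of 25 (median -0.26, adjusted p = 0.0794). NAC044 is itself a member, and without it, a choice made after the data were seen, the list passed the threshold (median -0.29, adjusted p = 2.03e-06, and 0.00178 with an estimated correlation). NAC103 was at -1.96, CYCB1;1 at -0.70, PARP2 at -0.66 and TSO2 at -0.49, and the members that were higher were NAC044 itself and KRP6 (0.24). S phase genes were lower in 17 of 20, or 18 adjusted over the list alone (median -0.28, adjusted p = 0.000144, and 0.0101 with an estimated correlation), PCNA1, the DNA polymerase clamp, at -0.56 ± 0.06. Genes of G2 and mitosis were lower in 14 of 28 (median -0.17, adjusted p = 0.00225, and 0.0162 with an estimated correlation). Dawn clock genes had a median of 0.50 in the same libraries.

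Vascular markers were higher in the libraries labelled nac044-1 rab8d-2, xylem in 5 of 7 (median 0.71, adjusted p = 2.09e-11, and 0.000894 with an estimated correlation) and phloem in 4 of 6 (median 0.53, adjusted p = 0.00184, and 0.0179 with an estimated correlation), CESA4 at 0.79 ± 0.04 and SEOR2 at 1.03 ± 0.06. Genes of the unfolded protein response were lower in 5 of 7 (median -0.27, adjusted p = 0.00033, and 0.0179 with an estimated correlation), the chaperone gene BIP2 at -0.38 ± 0.02. Meristem genes were lower in 9 and higher in 2 of 19 (median -0.17, adjusted p = 0.0133, and 0.091 with an estimated correlation), with ERF115 at -2.33 ± 0.23 and ERF114 at -2.12 ± 0.13, and phosphate starvation genes higher in 5 and lower in 1 of 8 (median 0.31, adjusted p = 0.0312, and 0.128 with an estimated correlation). FRO5 (2.30 ± 0.25), LSU3 of the sulfur starvation response (2.19 ± 0.14) and SWEET11 (4.29-fold higher) were among the highest, and AT5G55270 (-3.62 ± 0.20), ORA47 (-2.16 ± 0.06) and WRKY28 (-2.14 ± 0.15) among the lowest. Touch and wounding genes, chosen after the data were seen, were lower in 9 and higher in 1 of 12 (median -0.32, adjusted p = 2.42e-09), and all 5 cold and dehydration genes were higher (median 0.90, adjusted p = 2.31e-11), both calls holding with an estimated correlation. In all, 4859 genes were higher and 3720 lower, a share of 56.6% higher that became 44.5% with upper quartile scaling.

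The comparison of nac085-1 rab8d-2 with rab8d-2 asks which changes of rab8d-2 move with NAC085. The DNA damage list was lower as a group, with 21 of 25 members lower and 1 higher, the same adjusted over the list alone (median -0.50, adjusted p = 0.00285, and 0.02 with an estimated correlation). Without NAC085 the median was -0.49 (adjusted p = 0.00277). NAC103 was at -1.76 ± 0.08, SMR5 at -1.22, RAD17 at -1.08 ± 0.06, BRCA1 at -1.06 ± 0.06 and PARP2 at -0.73. Genes of G2 and mitosis were lower in 21 and higher in 2 of 28 (median -0.35, adjusted p = 0.049, and 0.0657 with an estimated correlation) and S phase genes in 17 of 20 (median -0.26, adjusted p = 0.111). In the same libraries jasmonate genes had a median of -2.67, touch and wounding genes of -2.80 and cold and dehydration genes of 3.35.

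Markers of 4 root cell types were higher in nac085-1 rab8d-2 than in rab8d-2: all 7 xylem markers (median 0.99, adjusted p = 2.08e-06, and 0.0109 with an estimated correlation), 5 of 6 phloem markers, or 6 adjusted over the list alone (median 0.77, adjusted p = 0.00688, and 0.0289 with an estimated correlation), all 7 root hair markers (median 0.45, adjusted p = 0.046, and 0.146 with an estimated correlation) and 7 of 8 endodermis markers (median 0.45, adjusted p = 0.019, and 0.0589 with an estimated correlation). Cytokinin response genes were higher in 7 of 9 (median 0.69, adjusted p = 0.000189, and 0.0109 with an estimated correlation) and phosphate starvation genes in 6 of 8 (median 0.78, adjusted p = 0.00038, and 0.022 with an estimated correlation), the phosphate transporter gene PHT1;1 at 1.13 ± 0.03. Genes of the unfolded protein response were lower in 6 of 7 (median -0.58, adjusted p = 0.000189, and 0.02 with an estimated correlation), mitochondrial stress genes lower in 8 and higher in 5 of 15 (median -0.38, adjusted p = 0.000189, and 0.0289 with an estimated correlation) and salicylate defence genes lower in 3 of 4 (median -0.88, adjusted p = 0.00553, and 0.0289 with an estimated correlation). Plastid chaperones (7 of 12 lower, 3 higher, median -0.27), heat shock genes (4 of 6 lower, 1 higher, median -0.60) and oxidative stress genes (8 of 18 lower, 6 higher, median -0.12) had adjusted p values of 0.0184, 0.0454 and 0.00688, and of 0.0604, 0.0807 and 0.0965 with an estimated correlation. Photosynthesis genes were lower in 11 of 24 and higher in none (median -0.34, adjusted p = 0.324).

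ADH1 (4.73 ± 0.08), FRO5 (4.72 ± 0.17), RNS1 (4.19 ± 0.09) and the cold-induced genes KIN1 (4.04 ± 0.09) and LTI78 (3.35 ± 0.03) were among the highest in nac085-1 rab8d-2. ORA47 (-5.70 ± 0.10), ERF13 (-5.22 ± 0.11), WRKY40 (-5.02 ± 0.05) and the jasmonate synthesis genes LOX3 (-5.09 ± 0.08) and LOX4 (-4.79 ± 0.09) were among the lowest. Of the lists chosen after the data were seen, all 15 jasmonate genes (adjusted p = 3.52e-83) and all 12 touch and wounding genes (adjusted p = 6.57e-81) were lower and all 5 cold and dehydration genes higher (adjusted p = 2.66e-32), calls that held with an estimated correlation. Dawn clock genes were higher in 2 and lower in 1 of 6 (median 0.15, adjusted p = 0.946). In all, 6362 genes were higher and 6332 lower, with 1019 and 892 changed at least 2-fold.

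**Figure D4:**
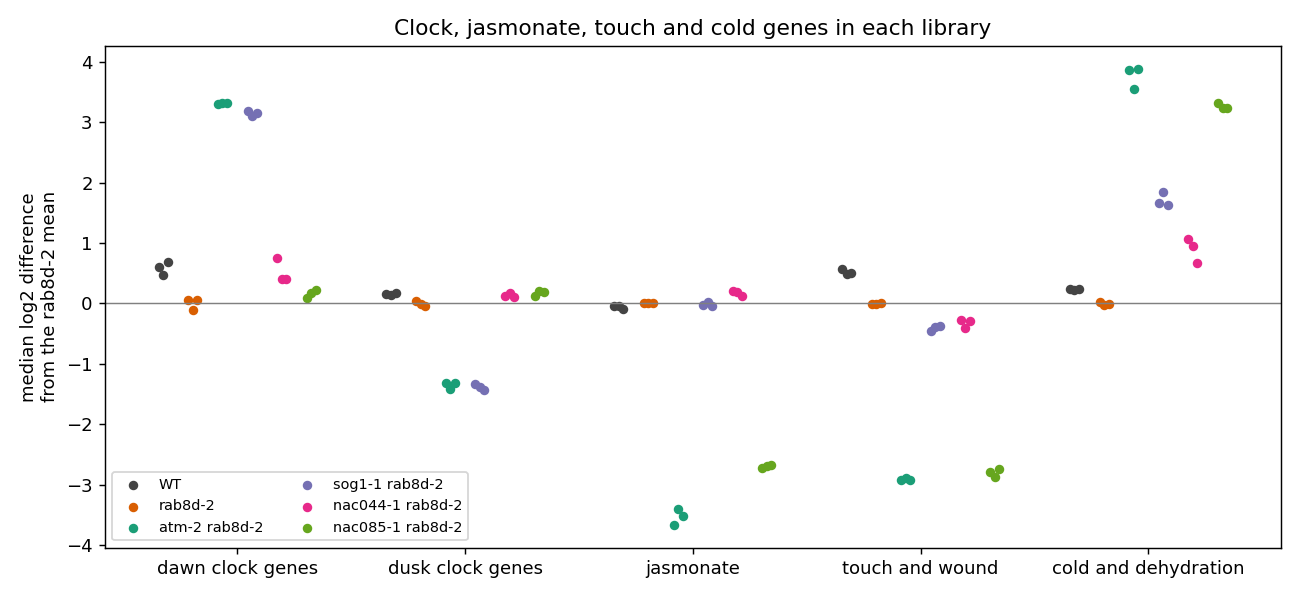
Median log2 difference of each library from the rab8d-2 mean (y axis) for 5 gene lists chosen after the data were seen (x axis), 1 point per library, 3 libraries per genotype. Dawn clock genes lie at 3.101 or above in every library of the atm-2 and sog1-1 double mutants, and touch and wounding genes at -2.74 or below in every library of the atm-2 and nac085-1 double mutants.

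In each double mutant part of the rab8d-2 changes moved back. Of the 821 genes raised at least 2-fold in rab8d-2, 400 (48.7%) were lower in atm-2 rab8d-2 than in rab8d-2, 386 (47.0%) in sog1-1 rab8d-2, 460 (56.0%) in the libraries labelled nac044-1 rab8d-2 and 453 (55.2%) in nac085-1 rab8d-2. Independent lists would give 245.3, 213.4, 152.9 and 260.2. Of the 1061 genes lowered at least 2-fold, 655 (61.7%), 737 (69.5%), 452 (42.6%) and 712 (67.1%) were higher in the same order, where independent lists would give 336.1, 304.0, 258.0 and 337.8. In 10 simulated data sets in which the double mutant equalled rab8d-2, at most 1 gene moved back. These data sets hold only the spread between libraries of a genotype. A deviation particular to the rab8d-2 libraries, or a difference in growth or harvest, would also be counted as moving back. Further from WT went 139, 135, 79 and 134 of the raised genes and 100, 50, 68 and 92 of the lowered genes, in the same order. In all 4 double mutants together, 195 of the raised and 257 of the lowered genes moved back, and 155 and 125 moved back in none. RAB8D itself is among the 257.

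**Figure D5:**
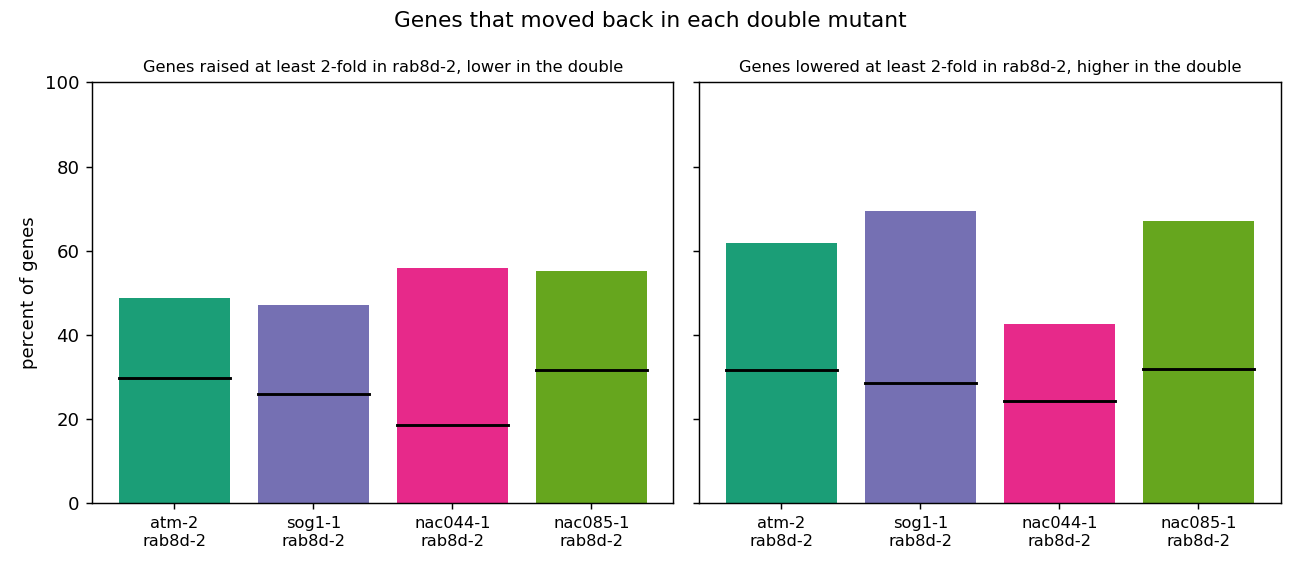
Percent of genes (y axis) changed at least 2-fold in rab8d-2 that changed the other way in each double mutant against rab8d-2 (x axis). Bars are raised genes on the left and lowered genes on the right, and the black line is the share that independent lists would give. The share of raised genes that moved back is 47.0% to 56.0%.

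Every pair of double mutants shared more changed genes than independent lists would. Of the 6 pairs, the atm-2 and nac085-1 double mutants shared the most, with 4329 genes lower and 4524 higher than in rab8d-2, where independent lists would give 1892 and 2015. The atm-2 and sog1-1 double mutants shared 2936 lower and 3476 higher, where independent lists would give 1552 and 1814. In 10 simulated data sets with no change no pair shared more than 1 gene in a direction. These too hold only the spread between libraries of a genotype. The overlap nearest to chance was that of the atm-2 and nac044-1 double mutants, with 1399 lower and 1871 higher, where independent lists would give 1111 and 1539. Of the genes changed at least 2-fold, the first pair shared 670 lower and 528 higher and the second 116 and 295, for which no simulated count at 2-fold was made. Every overlap rests on the same 3 rab8d-2 libraries.

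Against WT, the DNA damage list had a raised median in atm-2 rab8d-2, with 16 of 25 members higher and 2 lower (median 0.33, adjusted p = 0.0766), among them GMI1 at 1.52 and NAC044 at 1.48, with BRCA1 at -0.41. RNS1 was highest (7.82 ± 0.13), ABCA9 was at 6.03 ± 0.34, and RRTF1 was at -6.50 ± 0.05. AT3G45260 had 0 counts in atm-2 rab8d-2 and 307 in WT, at least 106-fold lower. Defence genes were lower in 4 of 4 (median -1.68, adjusted p = 0.000216, and 0.0243 with an estimated correlation). Heat shock (median -1.03), oxidative stress (median -0.37) and cytokinin response genes (median 0.66) were called with adjusted p values of 0.0098, 0.000216 and 0.014 and each had an adjusted p of 0.0532 with an estimated correlation. Dawn clock genes had a median of 2.76 and jasmonate genes of -3.29. In all, 7007 genes were higher and 6694 lower.

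Against WT, the DNA damage list in sog1-1 rab8d-2 was higher in 9 and lower in 5 of 25, or 8 and 5 adjusted over the list alone (median 0.06, adjusted p = 0.604). NAC044 was at 1.71, SMR5 at 1.38 and NAC103 at 1.12, while BRCA1 was at -0.67 and TSO2 at -0.44. Lists called with the preset correlation were plastid translation (median -0.31, 1 of 30 higher and 23 lower), plastid chaperones (median -0.20), heat shock (median -0.89), mitochondrial stress (median 0.65), defence (median -0.28) and cytokinin response (median 0.38). Their adjusted p values lay between 0.0432 and 0.0487, and between 0.159 and 0.203 with an estimated correlation. RNS1 (5.62 ± 0.20) and ABCA9 (5.36 ± 0.38) were among the highest, and MRD1 was at -6.66 ± 0.13. In all, 5764 genes were higher and 5837 lower, and dawn clock genes had a median of 2.60.

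Against WT, the libraries labelled nac044-1 rab8d-2 had 14 of 25 DNA damage genes higher and none lower (median 0.24, adjusted p = 5.1e-05, and 0.00318 with an estimated correlation). The call rests on NAC044 itself: without it 13 of 24 were higher, and the adjusted p was 0.0523 (median 0.23), or 0.135 with an estimated correlation. NAC044 was at 4.95 ± 0.06, GMI1 at 1.15 and PARP2 at 0.44, and NAC103 (0.21) was not called. Photosynthesis genes were lower in 21 of 24 (median -1.65, adjusted p = 3.14e-08, and 0.000535 with an estimated correlation). Mitochondrial stress (median 0.40), oxidative stress (median -0.04) and endodermis genes (median -0.37) had adjusted p values of 0.00123, 0.0324 and 0.0106, and of 0.112, 0.206 and 0.0784 with an estimated correlation. LHB1B2 was lowest (-4.62 ± 0.12). In all, 5849 genes were higher and 5756 lower.

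Against WT, nac085-1 rab8d-2 had 10 of 25 DNA damage genes higher and 4 lower (median 0.13, adjusted p = 0.421), with NAC044 at 1.33, GMI1 at 0.99, BRCA1 at -0.56 and SMR4 at -1.31. Photosynthesis genes were lower in 22 of 24 (median -2.098, adjusted p = 5.32e-05, and 0.00516 with an estimated correlation) and genes of plastid translation in 28 of 30 (median -0.57, adjusted p = 0.00956, and 0.0583 with an estimated correlation). Heat shock (median -1.11, adjusted p = 0.00335, and 0.0295 with an estimated correlation) and defence genes (median -1.29, adjusted p = 0.000277, and 0.0174 with an estimated correlation) were lower, and cytokinin response genes higher in 7 of 9 (median 0.65, adjusted p = 0.00185, and 0.023 with an estimated correlation). RNS1 was highest (7.42 ± 0.14) and ORA47 lowest (-6.13 ± 0.09). Jasmonate genes had a median of -2.58. In all, 6495 genes were higher and 6470 lower.

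The direct comparison of sog1-1 rab8d-2 with atm-2 rab8d-2 asks where the kinase and the transcription factor mutants part. DNA damage genes were lower in 14 and higher in 4 of 25 in sog1-1 rab8d-2 (median -0.26, adjusted p = 0.125), TSO2 being at -1.07, SMR7 at -1.02 and GMI1 at -0.86, with KRP6 at 0.84. Mitochondrial stress (median 0.35), oxidative stress (median 0.22) and defence genes (median 1.40) were higher, with adjusted p values of 0.000189, 0.00137 and 0.00448, and of 0.0954, 0.147 and 0.0954 with an estimated correlation. DDF1 was at 6.23 ± 0.08 and the zinc transporter gene ZIP1 at 5.88 ± 0.28. All 15 jasmonate genes were higher in sog1-1 rab8d-2 (median 3.36, adjusted p = 1.7e-89). In all, 5553 genes were higher and 5999 lower, with 1151 and 458 changed at least 2-fold.

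The direct comparison of nac085-1 rab8d-2 with the libraries labelled nac044-1 rab8d-2 was made by label, since no loss of NAC044 RNA was seen in the latter. Cytokinin response genes were higher in 9 of 9 in nac085-1 rab8d-2 (median 0.86, adjusted p = 3.93e-06, and 0.0047 with an estimated correlation). Mitochondrial stress genes were lower in 10 and higher in 2 of 15 (median -0.75, adjusted p = 3.93e-06, and 0.0353 with an estimated correlation) and heat shock genes lower in 5 and higher in 1 of 6 (median -0.98, adjusted p = 0.00606, and 0.0401 with an estimated correlation). Oxidative stress (median -0.25), defence (median -0.67) and phosphate starvation genes (median 0.50) had adjusted p values of 0.00715, 0.00715 and 0.0226, and of 0.124, 0.0516 and 0.124 with an estimated correlation. The DNA damage list was higher in 3 and lower in 10 of 25 (median -0.16, adjusted p = 0.0548), with an adjusted p of 0.612 when NAC044 and NAC085 were left out (median -0.12). ADH1 (3.65 ± 0.07) was highest, and DDF1 (-5.48 ± 0.06) and JAZ7, a jasmonate repressor gene (-5.02 ± 0.07), were lowest. Jasmonate genes had a median of -3.01. In all, 5856 genes were higher and 5825 lower, with 918 and 879 changed at least 2-fold.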

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

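The direct comparisons of the double mutants were planned, and the other tests in this part, with the bounds that decide them, were chosen after the results were seen. Groups of 3 libraries are too small for a check of single libraries that stand apart.

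In nac085-1 rab8d-2 and the libraries labelled nac044-1 rab8d-2, 3 gene lists had medians of opposite sign against rab8d-2, and the direct comparison passed the threshold for each. Against rab8d-2 itself none of these lists was called in the libraries labelled nac044-1 rab8d-2 (adjusted p = 0.0837, 0.342 and 0.23 in the order below), and the call of heat shock genes in nac085-1 rab8d-2 (adjusted p = 0.0454) was lost with an estimated correlation (adjusted p = 0.0807). Heat shock genes had medians of -0.60 and 0.35 and a direct difference of -0.98 (camera adjusted p = 0.00606, and 0.0401 with an estimated correlation). Mitochondrial stress genes had medians of -0.38 and 0.19 and a direct difference of -0.75 (adjusted p = 3.93e-06, and 0.0353 with an estimated correlation). Cytokinin response genes had medians of 0.69 and -0.17 and a direct difference of 0.86 (adjusted p = 3.93e-06, and 0.0047 with an estimated correlation). The genotypes also differ in the touch shift weighed below. Its library medians against rab8d-2 were -2.86 to -2.74 in nac085-1 rab8d-2 and -0.402 to -0.274 in the libraries labelled nac044-1 rab8d-2. The contrast of the 3 lists can therefore not be assigned to NAC085 and NAC044.

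DNA damage genes were higher in rab8d-2 than in WT. Without members that are cell cycle genes, their median was 0.62 against 0.13 for 48 genes of S phase and G2/M, a difference of 0.50. A permutation test over genes gave a two-sided p = 1e-05, the smallest that 100000 resamples can give. The permutation and Fisher's tests in this paragraph take genes as independent, although members of a list can move together. They do not measure the spread between plants or libraries. The gap between the medians argues against a larger share of dividing cells as the whole cause. The list median was at least 0.62 with DESeq2 size factors, upper quartile scaling, no filter, organelle genes left out and limma on TPM. The scalings moved the median of all genes by at most 0.0667, so they could not have brought it near 0 and decide nothing. A change of scale moves all genes of a library alike, so it would leave the difference of 0.50 from the cell cycle genes as it is. A difference in growth or harvest between rab8d-2 and WT was not tested. A candidate explanation is dependence of part of the rise on SOG1: 87.0% of the raised members (20 of 23) were lower in sog1-1 rab8d-2 than in rab8d-2, against 47.8% of other raised genes (Fisher's exact test, one-sided p = 0.000116, and 0.000463 after Benjamini-Hochberg over the 4 double mutants), while NAC044 (-0.20), NAC103 (-1.05) and SMR5 (-0.19, not called), singled out after their values were seen, were still 1.71, 1.12 and 1.38 above WT on the log2 scale. The same shares were 52.2% and 42.4% in atm-2 rab8d-2 (exact p = 0.229), 77.3% and 38.4% in the libraries labelled nac044-1 rab8d-2 (exact p = 0.000251) and 81.8% and 50.4% in nac085-1 rab8d-2 (exact p = 0.00246), and the clock shift in the sog1-1 libraries stays open as a further difference. Set against the cell cycle genes, the DNA damage median was lower by a difference of -0.28 in sog1-1 rab8d-2 (permutation p = 8e-05) and -0.19 in nac085-1 rab8d-2 (permutation p = 0.00064), while the difference of -0.05 in the libraries labelled nac044-1 rab8d-2 (permutation p = 0.32) and of -0.10 in atm-2 rab8d-2 (permutation p = 0.35) did not pass the threshold.

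Dawn clock genes were higher in the atm-2 and sog1-1 double mutants, and jasmonate and touch genes lower in the atm-2 and nac085-1 double mutants. A single harvest shared by the atm-2 and sog1-1 double mutants, apart from the others, cannot be judged from the jasmonate and touch genes. All 27 were higher in the sog1-1 than in the atm-2 double mutant, by a median of 3.34. These lists were chosen after their values were seen, and genotypes harvested together can still differ by mutation or handling. The time of day or handling at harvest and the effect of the second mutation cannot be told apart, because each genotype is 1 group whose libraries all shift: the lowest library median of the dawn genes in the atm-2 and sog1-1 double mutants was 3.101, and the library median of the touch genes nearest to 0 in the atm-2 and nac085-1 double mutants was -2.74. No harvest time is given in the sources used here. The other gene groups of these double mutants carry the same open question. It holds for rab8d-2 against WT too, at a smaller size. In the WT libraries the median of the touch genes lay 0.490 to 0.566 above rab8d-2. The dawn genes lay 0.469 to 0.679 above it there, and the jasmonate genes at -0.0880 to -0.0438.

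Genes lowered at least 4-fold in sog1-1 rab8d-2 lay near SOG1: 34 of 64 were among the 1000 tested genes on each side of it, where 6.41 would be by chance (Fisher's exact test, one-sided p = 6.47e-18), and 25 of 116 raised genes, where 11.6 would be (exact p = 0.000174). Loss of SOG1 activity alone is argued against by these 34 genes, since it gives no reason for a cluster around its own locus. Around the other second loci no excess was seen, with a smallest exact p of 0.201. Lowered genes numbered 32 near ATM, 1 near NAC044 and 16 near NAC085, where 32.6, 3.63 and 25.5 would be by chance. A cluster of a few genes near ATM or NAC085 would not show beside so many, and RAB8D was not tested. Clusters of marker genes next to any mutated locus are thus argued against only at the size seen around SOG1. A linked chromosome segment that differs from the other lines, carried along with the sog1-1 allele, is a candidate explanation: 26 of the 34 genes were lowest in all sog1-1 libraries, against 10 of the 30 lowered genes elsewhere (exact p = 0.000564), and 15 against 2 had 0 counts there (exact p = 0.000635). No sequence was available to test it.

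Each of the 11 comparisons has 10 splits of its 6 libraries into groups of 3, too few for a share under 0.05. The real split alone, 1 of the 10, gave as many genes in each. With the 6 libraries alone, the real split called 12942 genes for rab8d-2 against WT and the highest other 0. For the double mutants against rab8d-2 it called 12264 (atm-2), 10917 (sog1-1), 8612 (nac044-1) and 12585 (nac085-1), for those against WT 13671, 11548, 11606 and 12932 in the same order, and for the direct comparisons 11335 and 11614, with 0 as the highest other in each.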

How the results depend on the processing

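Leaving out genes of chromosome 1 and removing cell cycle members or mutated genes from the DNA damage list were chosen after the data were seen, and the other alternatives before. All 168 alternative counts of changed genes stayed within 1.5 times the main count, and no called gene or gene list that the text names changed sign. With upper quartile scaling the direction that held more of the changed genes switched in several comparisons, as for rab8d-2 against WT (49.1% to 56.6% higher) and the sog1-1 and nac044-1 double mutants against rab8d-2 (52.4% to 47.2% and 56.6% to 44.5%). With the replicate block the count of genes changed, rab8d-2 against WT, was 12892. Of the counts of genes changed at least 2-fold, 160 stayed within 1.5 times and 8 did not. These were 631 genes for sog1-1 rab8d-2 against rab8d-2 without chromosome 1 genes, which leaves fewer genes to count, and 7 counts with limma on log2(TPM + 1): 1106 (rab8d-2 against WT), 471, 168 and 1268 (the sog1-1, nac044-1 and nac085-1 double mutants against rab8d-2), 962 and 860 (sog1-1 and nac044-1 double mutants against WT) and 1161 (nac085-1 against nac044-1 double mutant). By construction the added pseudocount shrinks the fold changes of scarce genes, and no other cause was tested.

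Of the counts of reversed genes 140 stayed and 12 did not. With no minimum fold change, which admits more genes by construction, raised genes lower and lowered genes higher in the double mutant were 2682 and 3167 (atm-2), 3034 and 3478 (sog1-1), 2440 and 2892 (nac044-1), and 3194 and 3410 (nac085-1). With limma, 408, 424, 292 and 417 of 583 lowered genes were higher.

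The DNA damage list in atm-2 rab8d-2 against rab8d-2 passed the threshold with fry (median -0.28), with no filter (-0.28) and with limma (-0.19), with adjusted p values from 1.2e-10 to 0.297 over all alternatives. Its median ranged from -0.27 to -0.17 when single libraries were left out, the latter without rab8d-2 replicate 3 (adjusted p = 0.205). In the libraries labelled nac044-1 rab8d-2 it passed with fry (-0.26), with no filter (-0.26), with limma (-0.25) and without rab8d-2 replicate 3 (-0.26, adjusted p = 0.0444) and without its member NAC044 (-0.29 with both correlations), with medians from -0.32 to -0.25 when single libraries were left out and adjusted p values from 6.82e-07 to 0.17 over all alternatives. The fry test asks whether the genes move, not whether they move more than others, no filter adds scarce genes to the background, and NAC044 moved against the other members; the cause was not tested for the others. NAC085 in nac085-1 rab8d-2 ranged from -1.28 to -0.59 when single libraries were left out and lost its call without replicate 3 of nac085-1 rab8d-2 (adjusted p = 0.0506, and from 0.000388 to 0.0506 over all alternatives), at a mean of 18.7 counts per library.

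Counted over all values, including those above, 14379 for named genes kept their side of the threshold, 2 gained a call and 161 lost one. For gene lists 4435 kept their side, 302 gained a call and 95 lost one. Only 6 plastid and 5 mitochondrial identifiers passed the filter on low counts.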

Other observations

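Within the meristem list, members went both ways in rab8d-2 against WT. The stem cell niche gene WOX5 was at 2.05, the peptide gene RGF1 at 1.57 and ERF115, a regulator of stem cell replenishment, at 2.31, whereas the auxin exporter genes PIN4 and PIN7 were at -0.60 and -0.35. Against rab8d-2, ERF115 was at -2.33 and WOX5 at -0.64 in the libraries labelled nac044-1 rab8d-2, while WOX5 was at 1.67 and 1.74 in the atm-2 and nac085-1 double mutants. These genes were chosen after their values were seen.

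The first 3 principal components of the 18 libraries held 41.7%, 22.1% and 13.4% of the variance.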
